A study of Homo sapiens with 6 samples.

How the data were processed

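RNA from human primary fibroblasts was profiled on Illumina expression BeadChips, single-colour arrays that carry gene-specific probes on beads. The 6 samples fall into 2 groups of 3: cells transfected with a non-targeting siRNA (siNT) and cells transfected with an siRNA against GLD4 (siGLD4). GLD4 is a non-canonical poly(A) polymerase, also called PAPD5, whose current gene symbol is TENT4B. Per the labels' protocols, RNA was extracted with TRIzol and passed over a poly(U) column, and the fraction hybridised here was the one eluted at 65 °C. Poly(U) holds RNA by its poly(A) tail. A value therefore measures how much of a transcript was in this eluate, relative to the other transcripts. Tail length and total abundance both enter it, and no input or other fraction was analysed here. The normalization gave all arrays a common distribution of values. A gain or loss of RNA in the eluate as a whole would therefore not be seen. Nothing in the labels says that the replicates came from separate cultures or donors, so p-values measure the spread between these samples, which could be technical.

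The deposited table of non-normalized values holds, per the file headers, the mean bead signal intensity of each of 47323 probes and a detection column per array. The intensities are linear and not background-subtracted, and the submitters' processing notes name GenomeStudio 1.0. The deposited detection column is a fraction that rises with signal and reaches 1 for bright probes, so it was read as 1 minus the detection p, against its header. The authors' series value table is on a log2 scale. Differences between its arrays equalled those of log2 signal minus each array's 75th percentile, with a largest SD of 4.36e-07. A further baseline per probe had been subtracted in that table, which was not the median of these 6 arrays, and what it was set on stays unknown. Only differences between arrays were therefore used from it. Its column medians were 0.044, 0.050 and -0.019 in siNT replicates 1, 2 and 3, and -0.43, -0.028 and -0.051 in siGLD4 replicates 1, 2 and 3.

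Signals were processed with limma 3.58.1 in R 4.3.3. The neqc function applied a normexp background correction with negative-control parameters inferred from the detection p, an offset of 16, quantile normalization over all probes and a log2 transform. Probes with a detection p below 0.05 on all 3 arrays of at least 1 group were kept, 18569 in all. Of these, 13 on Y-linked or X-inactivation genes were left out. Names came from the platform's annotation, in which 30113 probes had 1 gene symbol, 8 had several and 17202 had none. Gene numbers matched 30074 of the single-symbol probes to current RefSeq symbols and changed 0 symbols. A gene was represented by its probe with the highest mean over all 6 arrays, and probes without a single symbol were kept as features of their own. This left 15002 features, 11039 of them named genes, of which 2878 had more than 1 kept probe.

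siGLD4 was compared with siNT by lmFit and eBayes with an intensity trend, with no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of a single gene cannot go below 0.1 with 3 against 3. Before the data were examined, 31 gene lists were fixed, and the 29 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with the correlation estimated from the data as a second value. The names in the text follow a rule fixed at the same time. TENT4B, its paralog TENT4A and the glucose transporter SLC2A1 were named whatever their values; 1 further gene of that rule, and 1 of the lists tested, are not reported here. Genes past the threshold were to be named next, and, since fewer than 5 passed in either direction, the 10 with the smallest unadjusted p in each direction were named instead. Up to 4 members of each list, those with the smallest unadjusted p, could be named as well. Where a probe was not above background on any array of 1 group, a fold is given as a lower bound against the lowest signal of a detected probe or the probe's own, whichever was higher. A probe's signal over background limits what can be measured, and the number of arrays limits the precision: the median standard error of a log2 fold change was 0.161.

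Alternatives fixed before the data were examined were 4 other background corrections or normalizations, the authors' log2 table, 2 other detection filters, the replicate number as a block, array weights, 2 other variance models, other rules from probes to genes, other thresholds, other set tests and leaving out each array. Scaling to equal medians over probes detected on all arrays was added after the data were seen, as were camera with an estimated correlation and fry under the other settings, and the adjustment over a list alone without each array. The slide could not be used as a block, since the labels and files used here do not give it. The code was tested on simulated data made from the mean signals of the real probes, in 5 draws with 200 changed genes each. Each array had a single noise SD, as measured in bright genes, and noise was drawn independently for each probe. Between 18098 and 18348 features passed the filter in these draws. Of changed genes that passed it, 29.5% were called at a true fold of 1.5, 78.8% at a fold of 2 and 91.6% at a fold of 3, and 3.96% of calls were false. Draws without changes gave 0 calls. Both lists given a shift of 0.3 on the log2 scale passed in all 5 draws, and 0 of the other lists did. Simulated genes of a list were not correlated, so these draws check the code and give no rate of false list calls for the real data. The shares of genes called likewise hold for the simulated noise.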

Results

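Transcripts in the 65 °C poly(U) eluate of human primary fibroblasts were measured on 6 Illumina BeadChips, 3 from cells given a non-targeting siRNA (siNT) and 3 from cells given an siRNA against GLD4 (siGLD4). Primary fibroblasts are connective-tissue cells grown directly from tissue. The comparison asks which transcripts differed in this eluate, relative to the other transcripts, when GLD4, a poly(A) polymerase, was depleted. Of 47323 probes, 19327, 19219 and 19470 were detected in siNT replicates 1, 2 and 3, and 21330, 20306 and 20308 in siGLD4 replicates 1, 2 and 3. The mean signal was 274.6, 269.2 and 319.3 in the siNT arrays and 397.9, 306.9 and 327.4 in the siGLD4 arrays. No pair of arrays was a copy: between 183 and 266 probes had equal signals in any pair. siGLD4 replicate 1 stood apart from the other arrays. The SD over genes of its deviation from the mean of the other 5 was 0.407 on the log2 scale, against 0.198 to 0.235 for the others, and the first principal component, with 49.5% of the variance, placed it at 41.7 and the others between -11.1 and -6.6. siNT replicate 3 lay nearer to siGLD4 replicates 2 and 3, with an SD of the difference over genes of 0.245 and 0.244, than to siNT replicates 1 and 2, with 0.263 and 0.291. The second component, with 20.5% of the variance, placed siNT replicates 1 and 2 at 12.4 and 18.9, siNT replicate 3 at -8.11 and siGLD4 replicates 2 and 3 at -6.75 and -15.6.

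TENT4B, the gene that encodes GLD4, was lower in all 3 siGLD4 arrays. Its normalized log2 intensity was 8.55 ± 0.0752 in siNT and 7.04 ± 0.268 in siGLD4 (SD, n = 3 each), a log2 fold change of -1.51 with a standard error of 0.161. The level in siGLD4 was 35.1% of that in siNT (limma, adjusted p = 0.0252). The gene was read by 1 probe, whose signal before normalization was 327.1, 342.3 and 396.4 in siNT and 196.1, 174.5 and 183.7 in siGLD4. TENT4A, the closest paralog and also a poly(A) polymerase, had a log2 fold change of -0.19 with a standard error of 0.138 and did not pass (limma, adjusted p = 0.757). It had -0.098 without siGLD4 replicate 1, and scaling to equal array medians turned its sign to 0.16, which is -0.11 relative to the median of all genes. Among 31 measured genes of poly(A) tail synthesis and cytoplasmic polyadenylation, TENT4B was the only one to pass, over all genes and adjusted over the list alone. TENT2, the poly(A) polymerase GLD2, and CPEB4, an RNA-binding regulator of cytoplasmic polyadenylation, had log2 fold changes of 0.28 and 0.44 and did not pass. The TENT4B call was lost without siNT replicate 1, 2 or 3, with limma adjusted p of 0.420, 0.559 and 0.410, and without siGLD4 replicate 2 or 3, with 0.0976 and 0.0641, while its log2 fold change stayed between -1.59 and -1.37 in the 6 such fits. It was also lost with equal array medians, at -1.17 and an adjusted p of 0.441, and without an intensity trend, at an adjusted p of 0.0505.

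**Figure D1:**
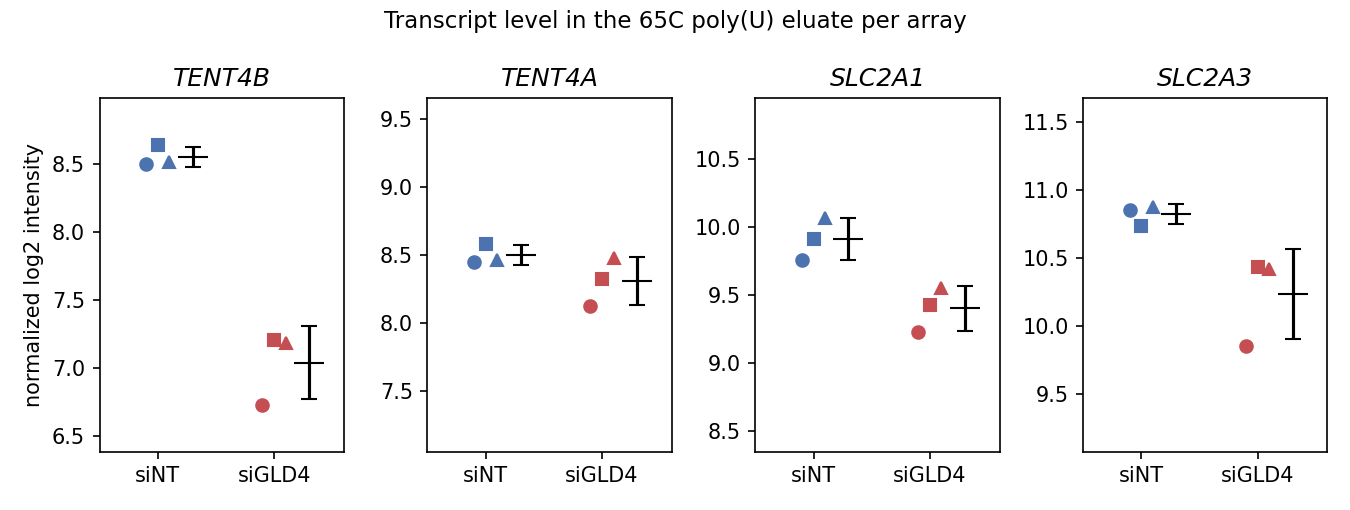
Normalized log2 intensity (vertical axes, each spanning the same range) of TENT4B, its paralog TENT4A and the glucose transporters SLC2A1 and SLC2A3 in the 3 siNT and 3 siGLD4 arrays. Points are arrays, with circles, squares and triangles for replicates 1, 2 and 3, and bars are the mean and SD; TENT4B was 8.55 in siNT and 7.04 in siGLD4, and in SLC2A1 and SLC2A3 the groups do not overlap.

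TENT4B was the 1 gene of 15002 features tested that passed, so 0 genes were higher and 1 was lower in siGLD4 (limma, adjusted p below 0.05). At an unadjusted p below 0.05 there were 505 features higher and 552 lower, 1057 together, where chance gives 750. Setting siNT replicates 1 and 2 and siGLD4 replicate 1 against the other 3 arrays gave more, 1470. The 2 groups did not overlap in 14.6% of features, where chance gives 10%. The adjusted p of the feature ranked second was 0.493. The genes named in the next sentences did not pass. Those with the smallest unadjusted p on the higher side included FOS and KLF4, transcription factors induced early after stimulation, with log2 fold changes of 0.81 and 0.70, although a second KLF4 probe gave 0.036. They also included ZFP36L1, a protein that binds AU-rich elements and promotes mRNA decay, at 0.53, PLAAT4, a phospholipase of the retinoid-inducible kind, at 0.90, and RPS28, a ribosomal protein, at 0.52. LRRN4CL, IGBP1 and the kinase ROCK1 had values of 0.72, 0.56 and 0.57, with 0.35 in a second ROCK1 probe. TBKBP1 and PLAC8 were not above background on any siNT array, and were at least 1.22-fold and 1.18-fold higher in siGLD4. On the lower side, SYNPO2L, an actin-associated protein, had a log2 fold change of -1.02, LCE2A, a protein of the cornified envelope, -1.03, and NPAS1, a transcription factor, -0.82. KRTAP3-1, a keratin-associated protein detected on 2 of 3 siGLD4 arrays, had -0.73, and FOLR3, a folate-binding protein, -0.72. SP140L had -0.70, the death-receptor family member TNFRSF21 -0.52, the magnesium-transporter-like NIPAL3 -0.45 and the BMP antagonist NBL1 -0.45, with -0.23 in a second NBL1 probe. Without siGLD4 replicate 1, SYNPO2L passed beside TENT4B, at -1.17 (limma, adjusted p = 0.00398). Weighting the arrays gave 7 calls, 2 higher and 5 lower, among them PLAAT4 and RPS28 higher and SYNPO2L, LCE2A and FOLR3 lower.

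Interferon-response genes were higher as a group, the 1 of 29 lists tested that passed (camera, adjusted p = 0.0337). With an estimated correlation the list did not pass (adjusted p = 0.701 with an estimated correlation). Under the 20 settings 0 lists did, and the lowest adjusted p was 0.448. This version is no clean test of inter-gene correlation, since camera p also rose in lists with an estimate below the preset 0.01. It went from 0.0110 to 0.0463 for glucose transport and glycolysis (-2.6e-04) and from 0.0252 to 0.0613 for the proteasome (-0.029). In the respiratory chain list (-0.0032) it fell from 0.489 to 0.421. For the interferon list the estimate was 0.080, above the preset 0.01, and camera p rose from 0.00116 to 0.121. How much of that rise came from correlation was not tested. A call lost with an estimated correlation therefore does not by itself show that correlation undid it. Whether any list could pass this version was not tested either, so the count of 0 does not count against a list. Of 34 measured members of the interferon list 26 had a positive and 8 a negative log2 fold change, with a median of 0.11. Singly 0 passed, over all genes or adjusted over the list alone. Its members with the smallest unadjusted p were DDX60, an antiviral helicase, at 0.53, IFIT1, which binds foreign RNA, at 0.28, IFI6, a mitochondrial interferon-induced protein, at 0.49, and USP18, the protease that removes ISG15, at 0.37. USP18 was detected on 1 of 3 siNT arrays and had 0.20 without siGLD4 replicate 1. IFI6 had 0.74 without siGLD4 replicate 3, and its second probe went the other way, at -0.55. The shift was not shared by the array that stood apart: the median difference of the list from the siNT mean was -0.012 in siGLD4 replicate 1, 0.25 in replicate 2 and 0.13 in replicate 3. Without siGLD4 replicate 1 the camera adjusted p was 1.32e-04; without siGLD4 replicate 2 or 3 it was 0.379 or 0.229, and without siNT replicate 1, 2 or 3 it was 0.141, 0.00529 or 0.144. The adjusted p was 0.0815 without a detection filter, 0.0678 with detection on all arrays, 0.0627 with the mean of a gene's probes and 0.0524 with equal array medians.

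**Figure D2:**
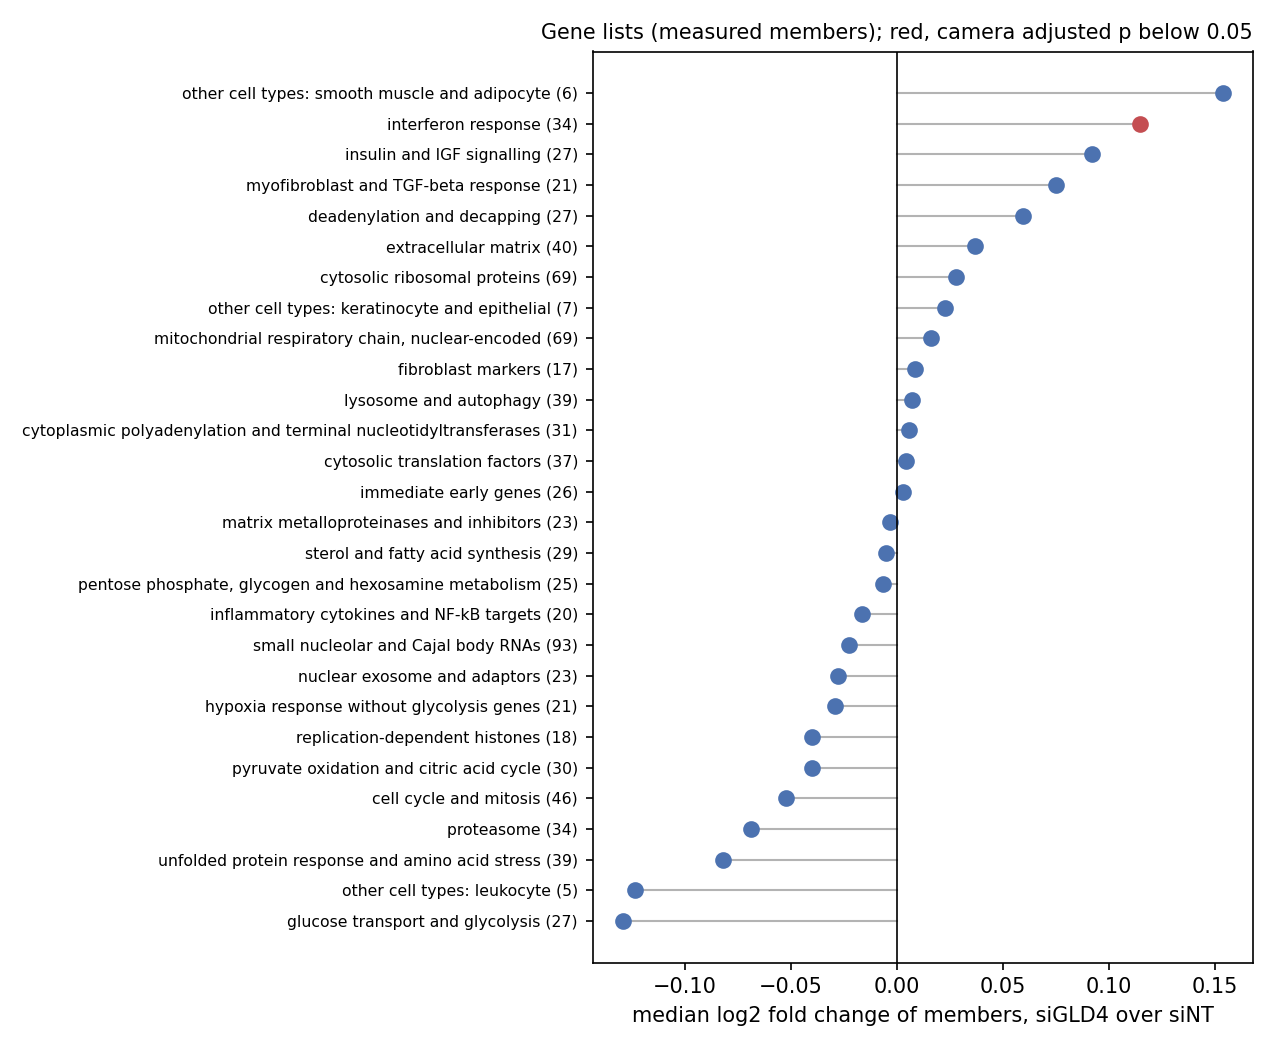
Median log2 fold change, siGLD4 over siNT (horizontal axis), of the measured members of each gene list reported (vertical axis, number of members in brackets). Red marks the list with a camera adjusted p below 0.05, interferon response, with a median of 0.11; the lowest median, -0.13, belongs to glucose transport and glycolysis, which did not pass.

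The glucose transporters SLC2A1 and SLC2A3 had the smallest unadjusted p in the glucose transport and glycolysis list, which did not pass as a whole (camera, adjusted p = 0.160; adjusted p = 0.701 with an estimated correlation). SLC2A1, the basal glucose transporter GLUT1, was 9.91 ± 0.157 in siNT and 9.41 ± 0.165 in siGLD4 (SD, n = 3 each), a log2 fold change of -0.51 with a standard error of 0.134. SLC2A3, the transporter GLUT3, had a log2 fold change of -0.59 with a standard error of 0.155. Neither passed over all genes, where the limma adjusted p was 0.701 for each. Adjusted over the list alone, these 2 of 27 members passed, with an adjusted p of 0.0425 each. Without siNT replicate 1, 2 or 3 that adjusted p was 0.128, 0.176 and 0.180 for SLC2A1 and 0.209, 0.176 and 0.180 for SLC2A3, and without siGLD4 replicate 2 it was 0.0716 and 0.0613. SLC2A6, a lysosomal hexose transporter, had -0.42, and PFKFB3, the enzyme that makes the glycolytic activator fructose 2,6-bisphosphate, had -0.35, with -0.11 in a second probe. SLC2A6 had -0.28 without siGLD4 replicate 1. Of the 27 members 17 had a negative and 10 a positive log2 fold change, with a median of -0.13, which was -0.071 without siNT replicate 1. The median difference from the siNT mean was -0.15, -0.071 and -0.14 in siGLD4 replicates 1, 2 and 3. The list passed without siGLD4 replicate 1 (camera, adjusted p = 0.00411), with array weights, at 0.0112, and with medians set equal over detected probes, at 0.0225; with an estimated correlation these adjusted p were 0.513, 0.448 and 0.967. Its adjusted p was 0.332 with equal array medians, 0.277, 0.249 and 0.156 without siNT replicate 1, 2 or 3, and 0.211 and 0.299 without siGLD4 replicate 2 or 3.

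Genes of the unfolded protein response and amino acid stress, of the proteasome and of the cell cycle had negative medians and did not pass (camera, adjusted p = 0.163 for each list). In the first, 25 of 39 members had a negative log2 fold change, with a median of -0.082; the endoplasmic reticulum chaperones CANX and HSPA5 had -0.46 (-0.70 in a second CANX probe) and -0.28, the co-chaperone DNAJC3 -0.40 and the secreted stress factor MANF -0.34. HSPA5 turned to 0.017 under equal array medians, which is -0.25 relative to the median of all genes. The siGLD4 arrays differed in this list, with medians of -0.24 in replicate 1, -0.017 in replicate 2 and -0.098 in replicate 3. Of 34 proteasome subunits 23 were negative, with a median of -0.069; PSMC1 had -0.25, with -0.027 in a second probe, and PSMD8 -0.36. By fry, which asks whether a list's genes move one way on balance without comparing them with other genes, the proteasome list was the 1 that passed (adjusted p = 0.00175), while camera gave it an adjusted p = 0.701 with an estimated correlation. The fry call was lost with cyclic loess, at an adjusted p of 0.394 and a median of -0.025, with equal medians over detected probes, at 0.482 and -0.16, with the authors' value table, at 0.936, and with the replicate block, at 0.0630. Equal array medians turned the list's median to 0.19, below the median of all genes, at a fry adjusted p of 0.352. Of 46 cell cycle genes 30 were negative, with a median of -0.052, among them the mitotic regulators BIRC5 at -0.56, PLK1 at -0.52 and CDC20 at -0.29, and the cyclin-dependent kinase subunit CKS1B at -0.22. Second probes of BIRC5 and CKS1B gave -0.38 and -0.17. CKS1B had 0.033 under equal array medians, which is -0.24 relative to the median of all genes. Without siGLD4 replicate 1 the medians of the unfolded protein and proteasome lists were -0.036 and -0.035, PSMD8 had -0.21 and CDC20 -0.17. The cell cycle median was -0.083 without siNT replicate 2, and -0.082, -0.093 and -0.10 without siGLD4 replicate 1, 2 or 3.

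**Figure D3:**
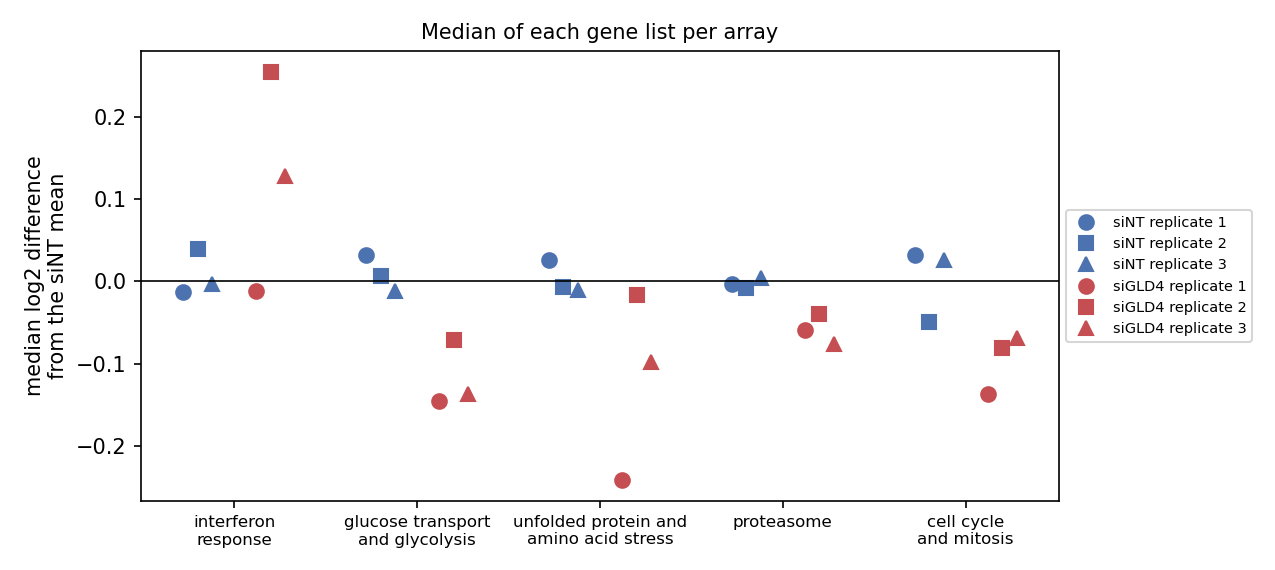
Median over the members of each of 5 gene lists (horizontal axis) of the log2 difference from the siNT mean (vertical axis) in each array, siNT in blue and siGLD4 in red. Circles, squares and triangles are replicates 1, 2 and 3; in the interferon response siGLD4 replicate 1 lies at -0.012 and replicates 2 and 3 at 0.25 and 0.13, and in the unfolded protein list replicate 1 lies lowest, at -0.24.

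The other 24 lists had camera adjusted p from 0.262 to 0.966, and 0 of them passed. Leaving out 1 array turned the sign of the median in 21 of these 24 lists, all but deadenylation and decapping, insulin and IGF signalling, and smooth muscle and adipocyte markers. Markers of other cell types were few: 7 keratinocyte and epithelial genes were measured with a median of 0.023, 5 leukocyte genes with a median of -0.12 and 6 smooth muscle and adipocyte genes with a median of 0.15, and 0 of these genes passed. The leukocyte median was 0.11 without siGLD4 replicate 3 and 0.15 with the mean of a gene's probes, and the smooth muscle and adipocyte median was 0.095 without siGLD4 replicate 1. Endothelial and melanocyte or neural markers had 2 measured members each and were not tested. The 17 fibroblast markers had a median of 0.0086. Small medians also came from cytosolic ribosomal proteins (0.028 over 69 genes), translation factors (0.0043 over 37), nuclear-encoded respiratory chain genes (0.016 over 69), extracellular matrix genes (0.037 over 40) and the nuclear exosome with its adaptors (-0.028 over 23). Insulin and IGF signalling had a median of 0.092 over 27 genes, the myofibroblast and TGF-beta response 0.075 over 21, and replication-dependent histones -0.040 over 18. These 3 medians were 0.016, -0.025 and 0.0040 without siGLD4 replicate 1. Hypoxia-response genes outside glycolysis had a median of -0.029 over 21 genes, which was 0.018 without siGLD4 replicate 1, and pentose phosphate, glycogen and hexosamine metabolism -0.0066 over 25. For 5 lists the sign of the median, the mean and the test were not all alike: sterol and fatty acid synthesis (median -0.0052 over 29), pyruvate oxidation and the citric acid cycle (-0.040 over 30), matrix metalloproteinases (-0.0031 over 23), lysosome and autophagy (0.0071 over 39) and cytoplasmic polyadenylation (0.0059 over 31). The cytoplasmic polyadenylation list includes the siRNA target TENT4B at -1.51, which lowers its mean of -0.037.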

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

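The choices added after the data were seen were scaling to equal medians over detected probes, the estimated correlation and fry under the other settings, and the adjustment over a list alone without 1 array. TENT4B stayed lower under each alternative, with log2 fold changes from -1.52 to -1.17 and limma adjusted p from 3.72e-05 to 0.441 when all arrays were kept, and from -1.59 to -1.37 with adjusted p from 1.71e-04 to 0.559 when 1 array was left out. It no longer passed with equal array medians, at -1.17 (adjusted p = 0.441), or without the intensity trend, at -1.51 (adjusted p = 0.0505). Under these 2 settings limma called 0 genes, with 1584 and 1082 features at an unadjusted p below 0.05; the cause was not tested. Array weights gave 7 calls, and the count ranged from 0 to 2 when 1 array was left out. All other settings gave 1 call, among them every probe on its own, an adjusted p below 0.1 and a minimum of 1.5-fold. The count of lists that passed was 0 with equal array medians, without a detection filter, with detection p below 0.01 on all 6 arrays, with the mean of a gene's probes and with camera at an estimated correlation; the cause was not tested. It was 2 with equal medians over detected probes and with array weights, where glucose transport and glycolysis also passed, and 3 with the authors' value table, where deadenylation and decapping (higher) and small nucleolar RNAs (lower, median -0.14) also passed. It ranged from 0 to 2 when 1 array was left out. Equal array medians moved the median of all genes to 0.27, against -0.078 to 0.0071 under the other settings, and turned TENT4A to 0.16, CKS1B to 0.033 and HSPA5 to 0.017; relative to that median, 0 of the named genes changed sign. The mean of both probes turned IFI6 to -0.030. Of 1074 values of the 57 other named genes under alternatives, 1064 kept their direction and their side of the threshold and 6 came to pass it. A further 9 values could not be had under a filter. None of the 57 passed in the main fit, so keeping their side means not passing again. Most were named for a small p in these same data, which favours a stable sign, so this count does not measure robustness. The labels do not say that a shared replicate number means a shared culture or day, so the main fit had no block. Deviations of arrays with the same replicate number correlated at 0.055, -0.023 and 0.20 over genes. For arrays of different groups and different numbers the correlations lay between -0.16 and 0.12. With the replicate block TENT4B was at -1.51 (adjusted p = 0.0186), and the block gave 1 call and 1 list, as without it, while the fry call of the proteasome list was lost (adjusted p = 0.0630). The slide as a block was not run. Genes near background have compressed fold changes, since a dim probe's signal is partly background.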

Other observations

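The tests after cyclic loess, against hypoxia genes, with an estimated correlation on the authors' value table, by fry under other settings and over a list alone without 1 array were chosen after the values were seen. The genes in this paragraph were among those with the smallest unadjusted p in their lists, and none passed (limma, adjusted p = 0.701 for each). Among inflammatory cytokine genes, the neutrophil chemokine CXCL8 had a log2 fold change of -0.60, the cytokine IL11 -0.59 and the hyaluronan-binding TNFAIP6 -0.45, while the mitochondrial superoxide dismutase SOD2 had 0.33. Second probes gave -0.28 for CXCL8 and 0.081 for SOD2, and the list of 20 had a median of -0.016 (camera, adjusted p = 0.883), which was -0.098 without siNT replicate 3 and 0.058 without siNT replicate 2. EIF4E, the mRNA cap-binding translation factor, had 0.86 with a standard error of 0.221. Lysosomal genes included ATP6V0E1, a proton pump subunit, at -0.35, and the cathepsins CTSL and CTSB at -0.30 and -0.32. Their other probes showed less: -0.13 for ATP6V0E1, -0.13 for CTSB, and -0.15 and 0.019 for CTSL. LOX, the collagen cross-linking enzyme, had -0.30, and POSTN, a matrix protein, 0.46, with 0.34 in a second probe. LMOD1, an actin nucleator of smooth muscle, had 0.46. The values of POSTN, CTSL and CTSB were 0.25, -0.19 and -0.21 without siGLD4 replicate 1.

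Among 93 small nucleolar and Cajal body RNAs, 41 had a positive and 52 a negative log2 fold change, with a median of -0.022 (camera, adjusted p = 0.838). Which form of these RNAs, mature or precursor, the column held was not measured. With the authors' value table this list was lower, with a median of -0.14 (camera, adjusted p = 0.0181), but not with an estimated correlation (adjusted p = 0.974 with an estimated correlation). In that table, the median in siGLD4 replicate 1 was -0.52 over probes whose detection p lay far above 0.05 on all arrays. In siGLD4 replicates 2 and 3 it was -0.049 and -0.096. Whether this shift of dim probes lowered the list there was not tested. From the scanner signals the list median was -0.064 without siNT replicate 1, -0.073 without siGLD4 replicate 3 and 0.00038 without siGLD4 replicate 1. SCARNA9, a guide RNA of Cajal bodies, had -0.62 and SNORA73B, a small nucleolar RNA, -0.64, with -0.29 in a second probe. In the other direction, SNORD21 and SNORA68 were not above background on any siNT array and were at least 1.16-fold and 1.29-fold higher in siGLD4; 0 of these 4 RNAs passed. In the list of 27 deadenylation and decapping genes, with a median of 0.060 (camera, adjusted p = 0.264), ZFP36L1 at 0.53 was the 1 gene that passed when adjusted over the list alone, and CNOT6L, a deadenylase, had 0.38. With the authors' value table that list was higher, with a median of 0.075 (camera, adjusted p = 0.0348), but not with an estimated correlation (adjusted p = 0.974 with an estimated correlation). From the scanner signals its median was 0.11 without siNT replicate 1, 0.020 without siNT replicate 2 and 0.031 without siGLD4 replicate 1. By fry the list passed with cyclic loess, with the mean of a gene's probes and without siGLD4 replicate 1 (adjusted p of 0.0171, 0.0371 and 0.00696), against 0.144 with quantile normalization and all arrays. ZFP36L1 no longer passed over the list alone without siNT replicate 1, 2 or 3 or siGLD4 replicate 3, with limma adjusted p of 0.206, 0.158, 0.0639 and 0.0836. Adjusted over the list of 26 immediate early genes alone, FOS at 0.81 and KLF4 at 0.70 passed as higher. SRF, the serum response factor, passed as lower at -0.44. Over all genes none of them passed (limma, adjusted p = 0.701 for each), and a second KLF4 probe gave 0.036. Adjustment over a list alone does not correct for the number of lists. The list median was 0.0028 (camera, adjusted p = 0.902), which was 0.075 without siNT replicate 1 and -0.040 without siNT replicate 3. FOS and KLF4 no longer passed over the list alone without siNT replicate 2 or 3, with limma adjusted p of 0.0587 and 0.0865 for both. SRF no longer passed without siNT replicate 1, 2 or 3 or siGLD4 replicate 3, with 0.172, 0.147, 0.0865 and 0.117.

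siGLD4 replicate 1 departed from the other arrays, and it was also the brightest. Before normalization, brightness accounted for 11.3% of the variance of its deviation over genes. After cyclic loess, which removed most of that trend, the SD of its deviation was still 1.89 times the highest among the other arrays, which argues against a trend with signal as the whole cause. Errors of single probes remain open: the deviation of 2 probes of a gene correlated at 0.168 over 2878 genes, against 0.150 to 0.313 in the other arrays. A stronger form of the response of the other siGLD4 arrays remains open too. With separate controls on each side its change correlated with theirs at -0.051 to 0.161 over genes, which are not independent replicates. The same measure gave -0.063 to 0.215 for siGLD4 replicates 2 and 3, so a low correlation was not particular to replicate 1.

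The higher interferon list was followed by a second list of 48 measured interferon-inducible genes with no member in the first. It was also higher by camera (p = 0.0311), with a median of 0.047 and 28 members above 0, but not with an estimated correlation (p = 0.112). Its median difference from the siNT mean was -0.020, 0.12 and 0.024 in siGLD4 replicates 1, 2 and 3, so the rise lay mainly in replicate 2. Both lists were measured on the same 6 arrays, so the second is no independent evidence for the first. A small rise of interferon-inducible genes as a class, not seen in every siGLD4 array, is a hypothesis these values are consistent with; whether it would come from the loss of GLD4 or from the siRNA itself was not tested. The 10 splits of the 6 arrays are too few for a share under 0.05: the real split passed 1 list and the highest other passed 2, and 3 of the 10 splits passed at least 1. The real split called 1 gene and the highest other called 2, with 2 of the 10 splits calling at least 1. At an unadjusted p below 0.05 the real split had 1057 features and the highest other, which set siNT replicates 1 and 2 and siGLD4 replicate 1 against the rest, had 1470.

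The glucose transport and glycolysis list, which did not pass, was divided into its 6 members of the SLC families, with a median of -0.31, and the 21 others. As SLC2A1 and SLC2A3 had been seen to be low, the value of the 6 members is no independent evidence. The 21 others, mainly enzymes, had a median of -0.093 with a camera p of 0.159. Without siGLD4 replicate 1 the camera p of these 21 was 0.00555, so whether the enzymes fell depends on that array and stays open. Hypoxia-response genes outside glycolysis had a median of -0.029 (0.018 without siGLD4 replicate 1), above that of the list by 0.10. The standard error set beside it, 0.0621, is that of a difference of means over list members. It measures the spread between genes and not between arrays, so a lower hypoxia response stays open. A candidate explanation, that SLC2A1 and SLC2A3 transcripts lose tail length or abundance when GLD4 is depleted, needs the input RNA or another elution fraction, neither of which was analysed here.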
